A study of Rattus norvegicus with 12 samples.

How the data were processed

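RNA was sequenced from 12 cultures of rat ovarian theca-interstitial cells, 4 cultures with vehicle, 4 with interleukin-1β (IL-1β) and 4 with lipopolysaccharide (LPS), after 48 h. The deposited table holds raw read counts per gene symbol, with 1 column for each library and no normalization by the authors. Per the submitters' processing notes, TopHat2 2.1.1, SAMtools and DESeq2 were used with the rat genome build Rnor_6.0. The notes name neither the program that counted the reads nor the gene annotation. They do not state how reads shared between similar gene copies were counted.

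The table held 30045 symbols, of which 1425 had no count in any library. Counts summed to between 20873934 and 32090924 per library. Pairs of rows were compared for near identity, meaning a correlation of at least 0.995 across libraries, a mean count of at least 50 and levels within 0.15 on the log2 scale. There were 335 such pairs over 607 rows, which held 9.78% of all counts. Some of them joined different genes of similar level, such as Gnb1 and Rac1, so not all pairs are copies. A numbered second copy of a symbol stood in 472 rows, some of which, such as Col1a2-2, were also in the pairs. All rows were kept, so reads of a gene with such a copy may stand in both rows. The copies of Hsd3b are similar in sequence, so counts of any one copy are uncertain.

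Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups given, which left 17330 genes. Libraries were scaled by TMM, with factors from 0.976 to 1.02, and a model with the 3 groups as its sole term was fitted to all 12 libraries (glmQLFit, robust). Contrasts were tested by quasi-likelihood F-tests, which are two-sided, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05 with no fold minimum. The biological coefficient of variation was 4.55%. The SE of a log2 fold change was its absolute value divided by the square root of F. CPM, counts scaled to a common library size, used the TMM-scaled totals. Ratios against groups with 1 to 3 counts in all carry an exact 95% interval, which covers counting error alone. The labels do not say whether replicates came from separate animals or separate isolations, so p-values measure only the spread between these samples.

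A total of 30 gene lists with 670 memberships were tested, covering steroid, cholesterol, inflammation, interferon, matrix and cell cycle genes and markers of cell types. Of the memberships, 654 matched a row, 8 of them under another name (for example Adgre1 as Emr1, Akr1c18 as Akr1c3 and Hsd3b2 as Hsd3b6). Hsd3b1 was not analysed here. The neutrophil list and the list of mitochondrially encoded genes had 0 members among the genes tested. Each list was tested against the other genes with camera in limma 3.58.1, with the preset correlation of 0.01, on log2 CPM with a prior count of 2. It was tested again with the correlation estimated for each list, and with fry, which asks whether a list's genes move one way on balance. Adjusted p-values of lists cover the lists tested within each comparison. Counts of members past the threshold are given over all genes tested and adjusted over the list alone, and where the text gives 1 count for a list both were the same.

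Named genes followed a rule: a panel of 30 genes, of which 29 matched, the 8 genes with the highest and the 8 with the lowest log2 fold change in each treatment, and the 5 each way between treatments. Genes ranked in this way had a mean of at least 2 CPM, an informative symbol and treated libraries all on the same side of the control libraries. From each list the 4 members with the smallest p were added as examples. Genes named outside the rule are marked as such. Some genes that the rule names are not reported here.

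Library properties were compared between groups by two-sided exact permutation tests over 70 arrangements, which cannot give a p under 0.0286. Overlap of the calls of both treatments was set beside the number for independent lists, beside 20 simulations of unchanged groups that share the controls, and beside fits with the 4 controls divided 2 and 2. Alternatives were DESeq2 size factors, upper-quartile factors, library size alone, no low-count filter, a stricter filter, DESeq2 1.42.0, limma-voom, fits on 8 libraries, a replicate block, the 10 most abundant genes left out, stricter thresholds, other set tests, and each library left out in turn. Lists with upper-quartile factors or library size alone were added after seeing the data. The procedure was tested on simulated data with the depths and spread of these libraries, but with far fewer genes changed than were called in the data. It called 48% of 25 genes changed 1.25-fold, 88% at 1.5-fold, 100% at 2-fold and 100% at 4-fold in the IL-1β setting, with 11 false calls. In the LPS setting it called 56%, 72% and 80%, with 7 false calls.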

Results

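Transcript levels were measured by sequencing of polyadenylated RNA from theca-interstitial cells, the androgen-producing cells of the ovarian follicle wall and stroma, taken from female Sprague Dawley rats on postnatal day 30. The cells grew on fibronectin and received vehicle, IL-1β, a cytokine of inflammation, or LPS, a bacterial cell wall component given at 1 µg/ml. Each group held 4 libraries. Total counts per library ran from 20873934 to 32090924 in control cultures, from 23193408 to 26836323 with IL-1β and from 25643226 to 28698783 with LPS. Ribosomal protein genes took 2.40% ± 0.0375 of counts (SD, n = 4) in control cultures, 2.63% ± 0.0236 with IL-1β and 2.57% ± 0.0210 with LPS. Both differences from control had the smallest p that the exact permutation test can give (0.0286, adjusted p = 0.171 over 12 comparisons). In a principal component analysis the first component, with 68.9% of the variance, separated treated from control libraries, and the next, with 12.8%, separated LPS from IL-1β. On that component LPS replicates 3 and 4 (-20.2 and -17.6) lay further out than LPS replicates 1 and 2 (-9.34 and -10.3).

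IL-1β was compared with control to ask how this cytokine shifts gene expression in the cells, with androgen production and proliferation named in the title of the study. Transcripts for androgen synthesis rose. Cyp17a1, whose enzyme turns progestins into androgens, went from 0.537 ± 0.101 to 15.5 ± 2.59 CPM (SD, n = 4), a 29.1-fold rise (log2 fold change 4.86 ± 0.31; after a log2 fold change ± stands for the SE, with 4 libraries per group). Cyp11a1, which cleaves the side chain of cholesterol, went from 3.55 ± 0.261 to 75.1 ± 7.12 CPM, or 21.1-fold (4.40 ± 0.13). Star, which carries cholesterol into mitochondria, rose 2.88-fold, from 141 ± 13.1 to 405 ± 15.0 CPM (1.52 ± 0.07). Of 13 androgen synthesis genes tested, 12 rose, 0 fell and 1 was not past the threshold, with a median log2 fold change of 1.52 (adjusted p = 1.95e-09, and adjusted p = 0.0337 with an estimated correlation). The examples were Hsd3b5 (3.04 ± 0.09), the electron carriers Fdx1 (1.92 ± 0.06) and Fdxr (1.28 ± 0.06), and Scarb1 (1.09 ± 0.05), a receptor for cholesterol from lipoproteins. Adjusted over the list alone, 12 rose as well.

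Genes that convert or inactivate steroids also rose with IL-1β, in 13 of 14 tested, with 0 lower (median 0.48, adjusted p = 2.55e-06, and 0.0206 as the adjusted p with an estimated correlation). They included Cyp7b1 (2.33 ± 0.08), an oxysterol hydroxylase, Akr1c1 (1.85 ± 0.11), Cyp1b1 (0.89 ± 0.05) and Hsd17b4 (0.32 ± 0.03). In cholesterol synthesis 21 of 25 genes rose and 0 fell over all genes tested, against 21 higher and 1 lower adjusted over the list alone. Its median was 0.44 (adjusted p = 8.97e-09, lost at adjusted p = 0.17 with an estimated correlation). Dhcr7 (0.79 ± 0.04), Hmgcs1 (0.66 ± 0.03) and Fdft1 (0.42 ± 0.03) were examples. Among theca identity genes 12 of 21 rose and 6 fell, and the list did not pass its test (median 0.26, adjusted p = 0.144). The luteinizing hormone receptor gene Lhcgr rose by 1.45 ± 0.14, Nr4a1 by 2.09 ± 0.07, Prlr by 1.53 ± 0.12, Igf1r by 0.45 ± 0.03 and Nr5a1 by 0.29 ± 0.04, while Gata4 changed by -0.31 ± 0.03. Insl3, a peptide hormone gene of theca cells, rose by 1.09 ± 0.34 (adjusted p = 0.0104), which was not called without IL-1β replicate 3 (0.82). Its level was low, with 4 to 8 counts per control library and 10 to 20 per IL-1β library.

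Among the genes with the highest folds with IL-1β, Reg3g, an antibacterial lectin, went from 0.120 ± 0.0916 to 59.2 ± 7.62 CPM (8.78 ± 0.22), and Reg3b rose by 7.13 ± 0.19. Reg1a had 3 counts in all 4 control libraries together, and its ratio of 232 had a 95% counting interval of 79.0 to 1128. Pla2g2a (6.31 ± 0.09), a secreted phospholipase, Hpx (6.11 ± 0.10), which binds haem, the chemokine gene Cxcl6 (5.83 ± 0.18), Lcn2 (5.64 ± 0.04), which binds iron carriers of bacteria, and Slpi (4.93 ± 0.24), a protease inhibitor, followed. The lowest values were those of Plin4, a lipid droplet protein gene, at -3.93 ± 0.20, Mybpc3 at -3.52 ± 0.09, Fabp4 at -3.32 ± 0.20, Tnnt2 at -3.24 ± 0.12, Fam180a at -2.75 ± 0.12, Capn6 at -2.73 ± 0.14, Lmod1 at -2.60 ± 0.10 and Mfap4 at -2.52 ± 0.08. The row of Mfap4 was nearly identical to that of an unnamed locus.

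Complement and acute phase genes rose with IL-1β in 16 of 21 and fell in 2 (median 1.17, adjusted p = 2.62e-08, lost at adjusted p = 0.0761 with an estimated correlation), among them C3 (2.93 ± 0.07), Steap4 (3.00 ± 0.11) and C1s (1.41 ± 0.04). Of 24 NF-kB feedback and target genes, 19 rose and 2 fell, or 20 and 2 adjusted over the list alone (median 0.74, adjusted p = 1.87e-09, lost at adjusted p = 0.0755 with an estimated correlation). Bcl3 (2.35 ± 0.06), Sod2 (2.09 ± 0.03), Nfkbiz (1.73 ± 0.06), Tnip1 (0.86 ± 0.03) and the inhibitor Nfkbia (0.82 ± 0.04) were members. Chemokine genes rose in 20 of 28 and fell in 6 (median 0.96, adjusted p = 4.7e-05, lost at adjusted p = 0.0806 with an estimated correlation). Ccl20 rose by 3.52 ± 0.24, Ccl6 by 3.27 ± 0.14, Ccl12 by 3.10 ± 0.13, Cxcl1 by 2.24 ± 0.09, Ccl2 by 2.05 ± 0.14 and Cxcl12 by 1.91 ± 0.04. Cytokine genes went both ways, 9 higher and 6 lower of 26, and the list did not pass (median 0.31, adjusted p = 0.413). Il6 (2.42 ± 0.24), Ereg (2.93 ± 0.26) and Tnfsf13b (2.62 ± 0.23) rose, Hbegf (-1.35 ± 0.07), Tgfb3 (-2.33 ± 0.06) and Il1rn (-0.69 ± 0.14) fell, and neither Tnf (-0.46 ± 0.29) nor Il1b itself (-0.06 ± 0.23) was past the threshold. Ptgs2, the inducible cyclooxygenase, rose by 1.58 ± 0.19 and Nos2, the inducible nitric oxide synthase, by 1.03 ± 0.09.

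Interferon response genes fell with IL-1β in 31 of 40 and rose in 3 (31 and 4 adjusted over the list alone), with a median of -0.42 (adjusted p = 1.75e-06, lost at adjusted p = 0.433 with an estimated correlation). Isg20 (-1.17 ± 0.09), Irf7 (-0.86 ± 0.11), Oas2 (-0.77 ± 0.10), Ifi44l (-0.40 ± 0.06) and Psmb8 (-0.35 ± 0.04) were among those lower. Of 8 genes of MHC class II presentation 3 fell, or 5 adjusted over the list alone, and the list did not pass (median -0.49, adjusted p = 0.151). Without Control replicate 3 the number lower was 5. Cd74, the invariant chain, fell (-0.43 ± 0.12). Collagen and matrix genes fell in 20 of 30 and rose in 6, with 22 lower adjusted over the list alone (median -0.53, adjusted p = 7.58e-06, lost at adjusted p = 0.296 with an estimated correlation). Examples were Fmod (-1.19 ± 0.07), Loxl2 (-1.08 ± 0.03), Sparc (-0.61 ± 0.03) and Col12a1 (-0.39 ± 0.03). Matrix proteases and inhibitors rose in 17 of 27 and fell in 7 (median 0.59, adjusted p = 0.0285, lost at adjusted p = 0.294 with an estimated correlation and at adjusted p = 0.073 with library size alone). Mmp9 (2.59 ± 0.12), Mmp13 (1.96 ± 0.44), Mmp3 (1.77 ± 0.18), Mmp16 (1.42 ± 0.09) and the inhibitor Timp1 (1.07 ± 0.03) rose, and Mmp14 fell (-0.57 ± 0.03). Mmp13 was barely detected, with 2 to 6 counts per control library and 8 to 18 per IL-1β library.

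Markers of other cell types moved with IL-1β as well. Macrophage markers fell in 11 of 19 and rose in 3, with 12 lower adjusted over the list alone (median -0.54, adjusted p = 0.00294, lost at adjusted p = 0.0806 with an estimated correlation). Emr1 (-1.57 ± 0.08), the leukocyte antigen Ptprc (-1.35 ± 0.12), Lyz2 (-1.03 ± 0.06) and Cd68 (-0.95 ± 0.07) were examples. Endothelial markers rose in 15 of 16 with 0 lower (median 1.07, adjusted p = 1.61e-08, lost at adjusted p = 0.237 with an estimated correlation), among them Vwf (2.12 ± 0.09), Emcn (1.54 ± 0.11), Sox17 (1.17 ± 0.10) and Sox18 (1.03 ± 0.09). Smooth muscle and pericyte markers fell in 10 of 14 and rose in 3 (median -1.11, adjusted p = 7.59e-05, lost at adjusted p = 0.159 with an estimated correlation). The contractile genes Actg2 (-2.38 ± 0.05), Myh11 (-2.00 ± 0.04), Cnn1 (-1.85 ± 0.08) and Tagln (-1.70 ± 0.04) were lower in every IL-1β library than in every control library.

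Cell cycle lists had small median shifts with IL-1β, though many of their mitosis and G1 genes passed the threshold. In G2 and mitosis 0 of 33 genes rose and 18 fell, or 20 adjusted over the list alone, with a median of -0.16 (adjusted p = 1.34e-04, lost at adjusted p = 0.433 with an estimated correlation). Kif23, a kinesin of cytokinesis, fell by 1.00 ± 0.06 on the log2 scale, and smaller falls were seen in Prc1 (-0.39 ± 0.05), Cdk1 (-0.37 ± 0.05), Anln (-0.30 ± 0.04) and the proliferation marker Mki67 (-0.23 ± 0.04). Ccnb1 stood at -0.14 ± 0.05 (adjusted p = 0.0182), a call lost without Control replicate 4 (-0.13), without IL-1β replicate 4 (-0.11) and with library size alone (-0.09). DNA replication genes were mostly not past the threshold, 24 of 32, with 2 higher and 6 lower (median -0.06, adjusted p = 0.151). Tyms (-0.39 ± 0.05), Pcna (-0.23 ± 0.05) and Uhrf1 (-0.21 ± 0.05) fell, and Hells, whose row was nearly identical to that of an unnamed locus, rose (0.45 ± 0.07). Among G1 cyclins and their inhibitors 6 of 20 rose and 11 fell (median -0.15, adjusted p = 0.226). Cyclin D1 (Ccnd1, 0.39 ± 0.08) and Myc (0.42 ± 0.04) rose, while the inhibitors Cdkn2b (-0.66 ± 0.04) and Cdkn1a (-0.42 ± 0.04), and Ccnd3 (-0.28 ± 0.04), fell.

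Over all genes, 4273 of 17330 were higher and 3988 lower with IL-1β, which is 47.7% of those tested. Most changes were small, with a median size of 0.32 on the log2 scale, and 666 genes rose and 409 fell at least 2-fold. In 44.2% of genes the IL-1β and control libraries did not overlap, against 2.86% given by chance. Calls higher made up 51.7% of all calls with TMM scaling and 64.1% with library size alone, which moved the median of all genes by 0.05. No called list or called named gene changed direction with DESeq2 size factors, upper-quartile factors or library size alone.

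LPS was compared with control to ask the same of a bacterial stimulus. Androgen synthesis rose here too, in 11 of 13 genes with 0 lower, or 12 adjusted over the list alone (median 1.33, adjusted p = 3.07e-08, and 0.0232 as the adjusted p with an estimated correlation). Cyp11a1 reached 31.7 ± 4.55 CPM (SD, n = 4), 8.92-fold over control (3.16 ± 0.14), Cyp17a1 3.39 ± 1.37 CPM, 6.39-fold (2.68 ± 0.39), and Star 353 ± 27.4 CPM, 2.51-fold (1.33 ± 0.07). Hsd3b5 rose by 1.84 ± 0.09 and Fdx1 by 1.39 ± 0.07. Steroid conversion genes rose in 10 of 14 with 0 lower (median 0.31, adjusted p = 5.43e-06, and 0.0103 as the adjusted p with an estimated correlation), among them Cyp7b1 (2.80 ± 0.07), Akr1c1 (1.84 ± 0.11), Cyp1b1 (1.33 ± 0.05) and Akr1c14 (0.78 ± 0.04). Cholesterol synthesis genes rose in 18 of 25 and fell in 2, with 20 higher adjusted over the list alone (median 0.21, adjusted p = 3.51e-05, lost at adjusted p = 0.296 with an estimated correlation). Idi1 (0.56 ± 0.05), Hsd17b7 (0.51 ± 0.05), Hmgcs1 (0.43 ± 0.03) and Dhcr7 (0.40 ± 0.04) were higher.

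Theca identity genes split under LPS, with 8 of 21 higher and 6 lower, or 10 and 7 adjusted over the list alone (median 0.00, adjusted p = 0.884). Nr4a1 (1.47 ± 0.07), Igf1r (0.30 ± 0.03) and Nr5a1 (0.16 ± 0.04) rose, and Gata4 (-0.34 ± 0.03) and the stromal factor Tcf21 (-0.72 ± 0.08) fell. Lhcgr, at 0.38 ± 0.16, was not past the threshold (adjusted p = 0.0535), and was called without LPS replicate 2 (0.42), without LPS replicate 3 (0.48) and in 3 other settings. Insl3 stood at 0.90 ± 0.35 (adjusted p = 0.0377), a call lost in 8 settings, including without any of the Control replicates (0.76 to 0.98), without LPS replicate 2 (0.75) and without LPS replicate 3 (0.83).

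**Figure D1:**
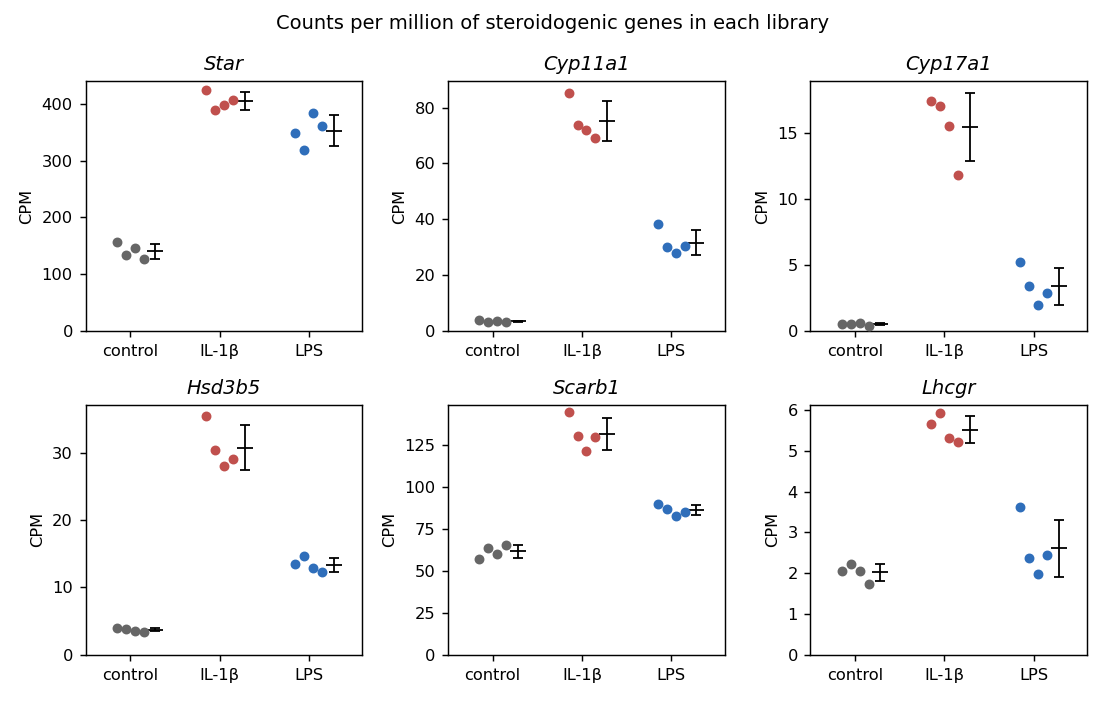
CPM of 6 steroidogenic genes in each of the 12 libraries, with points for libraries, a horizontal tick for the group mean and bars for the SD (n = 4 per group). Each vertical axis starts at 0. Cyp11a1 averaged 3.55 in control, 75.1 with IL-1β and 31.7 with LPS.

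The NF-kB, chemokine and cytokine lists were higher with LPS than in control. Of 24 NF-kB feedback and target genes 21 rose and 1 fell (median 1.18, adjusted p = 4.07e-16, and 0.0116 as the adjusted p with an estimated correlation), with Bcl3 at 2.35 ± 0.06, Sod2 at 2.32 ± 0.03, the deubiquitinase Tnfaip3 at 2.05 ± 0.04, Nfkbia at 1.28 ± 0.04 and Tnip1 at 1.09 ± 0.03. Chemokine genes rose in 21 of 28 and fell in 1 (median 1.48, adjusted p = 3.64e-11, and 0.0103 as the adjusted p with an estimated correlation). Cxcl6 (6.07 ± 0.17) and Cxcl2 (5.43 ± 0.22), both attractants of neutrophils, Ccl20 (4.38 ± 0.21), Cxcl1 (3.20 ± 0.09), Ccl2 (2.91 ± 0.14), Ccl3 (2.86 ± 0.14), Cxcl12 (1.67 ± 0.04) and Cxcl16 (1.02 ± 0.04) rose. Cytokine genes rose in 14 of 26 and fell in 3 (median 0.51, adjusted p = 0.0101, lost at adjusted p = 0.0841 with an estimated correlation). Il1b went from 0.889 ± 0.200 to 11.4 ± 0.455 CPM (SD, n = 4), 12.5-fold (3.65 ± 0.14), and Il1a (2.90 ± 0.14) and Il6 (2.69 ± 0.23) rose. Hbegf (-1.05 ± 0.06) and Tgfb3 (-2.42 ± 0.06) fell, and Tnf (0.46 ± 0.25) and Il1rn (0.04 ± 0.13) were not past the threshold. Nos2 rose 6.63-fold (2.73 ± 0.08) and Ptgs2 by 2.27 ± 0.18.

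The genes with the highest folds with LPS were Reg3g at 7.39 ± 0.26, the chemokine gene Cxcl6 at 6.07 ± 0.17, Pla2g2a at 6.03 ± 0.09, Hpx at 5.45 ± 0.10, Cxcl2 at 5.43 ± 0.22, Reg3b at 5.26 ± 0.25, Lcn2 at 4.99 ± 0.04, and Reg1a with a ratio of 43.8 and a counting interval of 14.7 to 215. Complement and acute phase genes rose in 16 of 21 and fell in 4, or 5 adjusted over the list alone (median 1.01, adjusted p = 3.82e-07, lost at adjusted p = 0.0604 with an estimated correlation). C3 (3.35 ± 0.07), Steap4 (2.77 ± 0.11) and C1s (1.41 ± 0.04) were among them. Interferon response genes went both ways, 7 higher and 7 lower of 40 (median -0.06, adjusted p = 0.608), with Gbp5 (1.12 ± 0.05), Irf8 (0.93 ± 0.14) and Irf1 (0.35 ± 0.05) higher and Isg20 (-0.81 ± 0.09) lower. The number lower was 12 without LPS replicate 3, and 3 or 4 without Control replicates 1, 2 or 4 or LPS replicates 1, 2 or 4. Irf7 stood at -0.35 ± 0.10 (adjusted p = 0.0216), which was not called without Control replicate 2 (-0.33), without LPS replicate 1 (-0.30), without LPS replicate 4 (-0.32) or with a replicate block (-0.35, adjusted p = 0.0582).

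Macrophage genes were among the lowest values with LPS. The complement component genes C1qc (-3.69 ± 0.22) and C1qa (-3.53 ± 0.14), made by macrophages, and the macrophage lectin Siglec1 (-3.37 ± 0.17) fell, and C1qa went from 7.06 ± 0.399 to 0.605 ± 0.161 CPM (SD, n = 4), 11.6-fold lower. Macrophage markers fell in 14 of 19 and rose in 1, with 16 lower adjusted over the list alone (median -1.11, adjusted p = 1.04e-08, and 0.00951 as the adjusted p with an estimated correlation), Lyz2 at -1.79 ± 0.06 and Cd68 at -1.25 ± 0.07 among them. Genes of MHC class II presentation fell in 7 of 8 (median -1.01, adjusted p = 0.00519, and 0.0461 as the adjusted p with an estimated correlation), among them RT1-DMb (-1.97 ± 0.21), RT1-Db1 (-1.46 ± 0.29), RT1-DMa (-0.96 ± 0.16) and Cd74 (-0.56 ± 0.12). The row of RT1-DMa was nearly identical to that of an unnamed locus. The other genes with the lowest values were Mybpc3 (-3.78 ± 0.09), Fabp4 (-2.76 ± 0.18), Tnnt2 (-2.70 ± 0.11), Capn6 (-2.53 ± 0.13) and Plin4 (-2.53 ± 0.16).

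Contractile and matrix genes fell with LPS. Smooth muscle and pericyte markers were lower in 11 of 14 with 0 higher, or 12 lower and 2 higher adjusted over the list alone (median -1.03, adjusted p = 5.32e-08, and 0.0452 as the adjusted p with an estimated correlation). Without LPS replicate 3, 2 were higher, and without LPS replicate 4, 1 was. Actg2 (-2.18 ± 0.05), Myh11 (-1.88 ± 0.04), Cnn1 (-1.71 ± 0.08) and Tagln (-1.33 ± 0.04) were examples. Collagen and matrix genes fell in 22 of 30 and rose in 5 (median -0.60, adjusted p = 3.07e-08, lost at adjusted p = 0.209 with an estimated correlation), with Postn (-1.63 ± 0.09), Loxl2 (-1.03 ± 0.03), Col12a1 (-0.67 ± 0.03) and Sparc (-0.66 ± 0.03) lower. Proteases and inhibitors did not pass as a list, with 12 of 27 higher and 8 lower (median 0.10, adjusted p = 0.357). Mmp9 (3.17 ± 0.12), Mmp3 (1.37 ± 0.18), Mmp16 (1.27 ± 0.09) and Timp1 (0.69 ± 0.03) rose, and Mmp14 fell (-0.41 ± 0.03). Mmp13, at 1.34 ± 0.48 (adjusted p = 0.0249), was not called without LPS replicate 3 (1.21), LPS replicate 4 (1.15), or Control replicates 1 (1.19), 2 (1.17) or 4 (1.21). Endothelial markers rose in 13 of 16 with 0 lower, or 14 adjusted over the list alone (median 0.71, adjusted p = 7.27e-06, lost at adjusted p = 0.296 with an estimated correlation), with Vwf at 1.20 ± 0.10, Emcn at 1.14 ± 0.11, Sox17 at 0.90 ± 0.10 and Cldn5 at 0.74 ± 0.11.

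Median shifts of the cell cycle lists were small with LPS too, though many of their mitosis and G1 genes passed the threshold. In G2 and mitosis 17 of 33 fell with 0 higher (median -0.15, adjusted p = 3.09e-04, lost at adjusted p = 0.534 with an estimated correlation), among them Kif23 (-0.82 ± 0.06), Cdk1 (-0.27 ± 0.05), Prc1 (-0.25 ± 0.05), Mki67 (-0.22 ± 0.04) and Anln (-0.21 ± 0.04). Of the 33, 9 fell without Control replicate 4 and 10 without LPS replicate 1. Ccnb1 (-0.07 ± 0.05) was not past the threshold. Of 32 DNA replication genes 2 rose and 5 fell, or 2 and 2 adjusted over the list alone (median -0.06, adjusted p = 0.493), with Hells (0.35 ± 0.07) and Mcm7 (0.16 ± 0.04) higher and Tyms (-0.19 ± 0.05) lower. The number lower was 10 without LPS replicate 3, 2 without LPS replicate 4, and 3 without Control replicates 1, 2 or 3 or LPS replicates 1 or 2, and the number higher was 4 without LPS replicate 2. Among G1 cyclins and inhibitors 5 of 20 rose and 9 fell, or 10 adjusted over the list alone (median -0.06, adjusted p = 0.493). The number higher was 2 without LPS replicate 1, and 3 without Control replicates 2 or 3 or LPS replicate 4. Myc (0.54 ± 0.04) rose and Cdkn2b (-0.49 ± 0.04) and Ccnd3 (-0.38 ± 0.04) fell. Ccnd1 (0.20 ± 0.08, adjusted p = 0.0367) and Pcna (-0.12 ± 0.05, adjusted p = 0.0449) were called, but Ccnd1 not without Control replicates 1, 2 or 3 or LPS replicates 1 or 4 (0.16 to 0.20), with upper-quartile factors (0.19) or with DESeq2 (0.19), and Pcna not without any 1 of 8 libraries (-0.12 to -0.10) or with library size alone (-0.08).

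**Figure D2:**
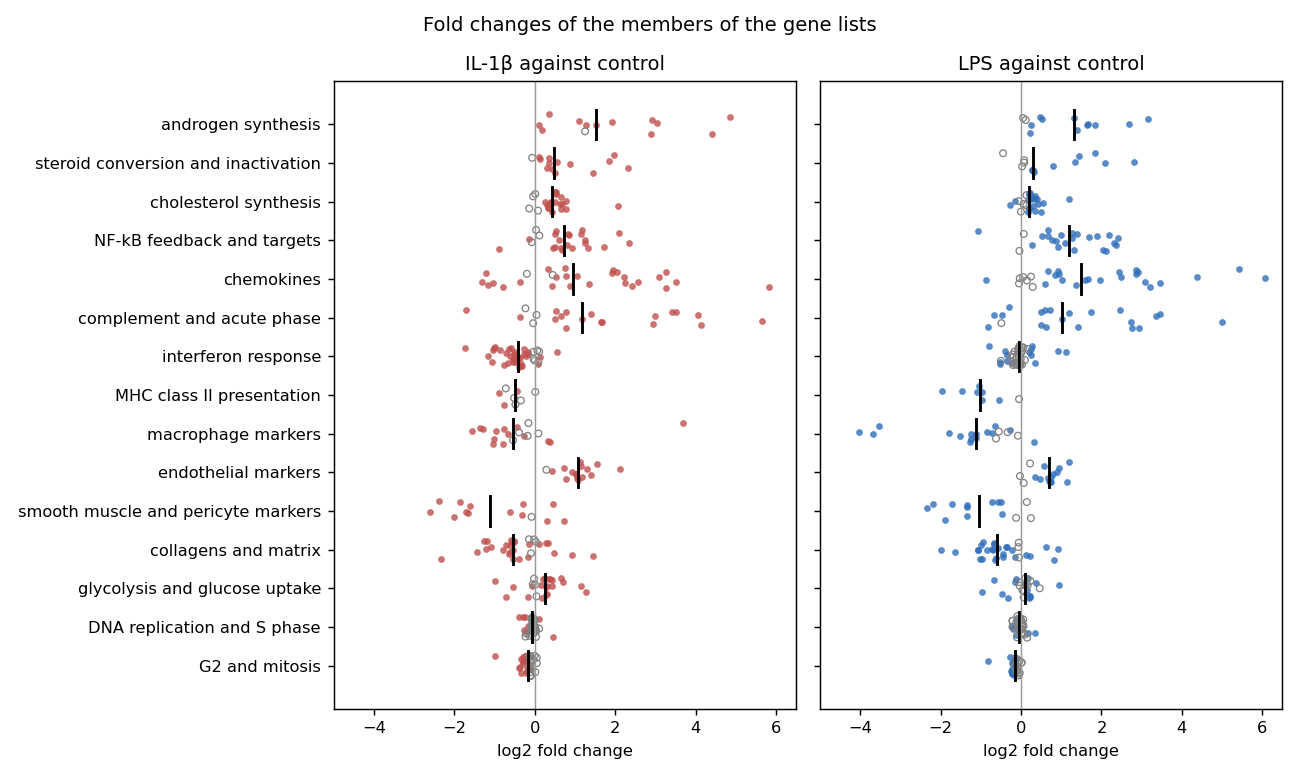
Log2 fold changes of the members of 15 gene lists with IL-1β (left) and LPS (right) against control, 4 libraries per group. Each point is a gene, filled where it passed an adjusted p of 0.05 and open where it did not, and the black bar is the list's median. The median of the androgen synthesis list stands at 1.52 and 1.33, that of the macrophage markers at -0.54 and -1.11.

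With LPS 3898 of 17330 genes were higher and 3460 lower, 42.5% of those tested, with a median size of 0.29 on the log2 scale. At least 2-fold changes numbered 398 higher and 387 lower. LPS and control libraries did not overlap in 38.4% of genes, against 2.86% by chance. Calls higher made up 53.0% of all calls with TMM and 63.4% with library size alone, which moved the median of all genes by 0.04.

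LPS was next compared with IL-1β directly, to test where the stimuli differ. Il1b reached 11.4 ± 0.455 CPM with LPS and 0.861 ± 0.331 with IL-1β (SD, n = 4), a 13.1-fold difference (3.71 ± 0.15). Irg1 (4.54 ± 0.22), the enzyme that makes itaconate, Il1a (2.52 ± 0.14), Ubd (2.35 ± 0.15), a ubiquitin-like protein, and Cxcl2 (2.15 ± 0.14) were the other genes highest under LPS. Lowest under LPS were the lectin gene Clec10a (-4.05 ± 0.19), C1qc (-3.24 ± 0.24), C1qa (-2.53 ± 0.16), Reg1a (-2.40 ± 0.16) and Cyp17a1 (-2.19 ± 0.21).

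Androgen synthesis genes were lower with LPS than with IL-1β in 9 of 13, with 0 higher and 10 lower adjusted over the list alone (median -0.75, adjusted p = 6.75e-10, and 0.0213 as the adjusted p with an estimated correlation). Besides Cyp17a1, these were Cyp11a1 (-1.24 ± 0.09), Hsd3b5 (-1.21 ± 0.07), Fdxr (-0.75 ± 0.06), Scarb1 (-0.61 ± 0.05) and Fdx1 (-0.54 ± 0.06) among others. Star, at -0.20 ± 0.07, was not past the threshold (adjusted p = 0.0686), but was called in 7 settings. These were without LPS replicate 3 (-0.24), without Control replicates 1 or 4 (-0.20 for both), and 4 other fits. The 4 were DESeq2, limma-voom, the fit on 8 libraries and the replicate block (-0.20 for each). Cholesterol synthesis genes were lower in 16 of 25 with 0 higher, or 23 lower adjusted over the list alone (median -0.18, adjusted p = 2e-10, lost at adjusted p = 0.136 with an estimated correlation), with Tm7sf2 (-0.53 ± 0.07), Ebp (-0.43 ± 0.06), Dhcr7 (-0.39 ± 0.04) and Hmgcs1 (-0.23 ± 0.03). Theca identity genes were lower in 9 of 21 and higher in 1, or 11 lower adjusted over the list alone (median -0.13, adjusted p = 0.00151, lost at adjusted p = 0.105 with an estimated correlation). Lhcgr (-1.08 ± 0.13), Nr0b1 (-0.82 ± 0.10), Nr4a1 (-0.62 ± 0.06), Ptch1 (-0.33 ± 0.05) and Nr5a1 (-0.13 ± 0.04) were lower, whereas Insl3 (-0.19 ± 0.30) was not past the threshold. Steroid conversion genes did not pass as a list, with 4 of 14 higher and 1 lower, or 4 and 2 adjusted over the list alone (median -0.03, although camera leaned upward, adjusted p = 0.664). Cyp7b1 (0.47 ± 0.06), Cyp1b1 (0.45 ± 0.05), Akr1c14 (0.23 ± 0.04) and Hsd11b1 (0.17 ± 0.04) were higher.

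NF-kB genes were higher with LPS than with IL-1β in 18 of 24 with 0 lower, or 19 adjusted over the list alone (median 0.35, adjusted p = 9.98e-15, and 0.0213 as the adjusted p with an estimated correlation). Vcam1 (1.26 ± 0.07), a leukocyte adhesion molecule, Tnfaip3 (0.80 ± 0.04), Tnfaip2 (0.60 ± 0.04), Birc3 (0.58 ± 0.04), Nfkbia (0.46 ± 0.04) and Sod2 (0.23 ± 0.03) were among them. Chemokine genes were higher in 16 of 28 and lower in 5, or 18 and 5 adjusted over the list alone (median 0.85, adjusted p = 1.11e-06, lost at adjusted p = 0.0503 with an estimated correlation). Ccl3 (1.80 ± 0.13), Cxcl1 (0.97 ± 0.08), Ccl2 (0.86 ± 0.12), Ccl20 (0.85 ± 0.13) and Cxcl16 (0.60 ± 0.04) were higher and Ccl6 lower (-1.91 ± 0.12). Cytokine genes were higher in 12 of 26 and lower in 3, or 13 and 4 adjusted over the list alone (median 0.27, adjusted p = 0.00255, lost at adjusted p = 0.0692 with an estimated correlation). They included Il10 (1.77 ± 0.29), Csf1 (0.77 ± 0.06), Il1rn (0.74 ± 0.14) and Tnf (0.92 ± 0.27), the last of which was not called without IL-1β replicate 2 (0.75). Without IL-1β replicate 2 or LPS replicate 4, 1 cytokine gene was lower. Il6 did not pass (0.26 ± 0.17). Interferon response genes were higher in 31 of 40 and lower in 2, or 35 and 2 adjusted over the list alone (median 0.37, adjusted p = 1.3e-14, lost at adjusted p = 0.219 with an estimated correlation), with Gbp5 (1.15 ± 0.05), Irf7 (0.51 ± 0.11), Gbp2 (0.48 ± 0.04), Psmb9 (0.41 ± 0.05) and Psmb8 (0.31 ± 0.04). Nos2 (1.70 ± 0.07) and Ptgs2 (0.69 ± 0.15) were higher too.

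**Figure D3:**
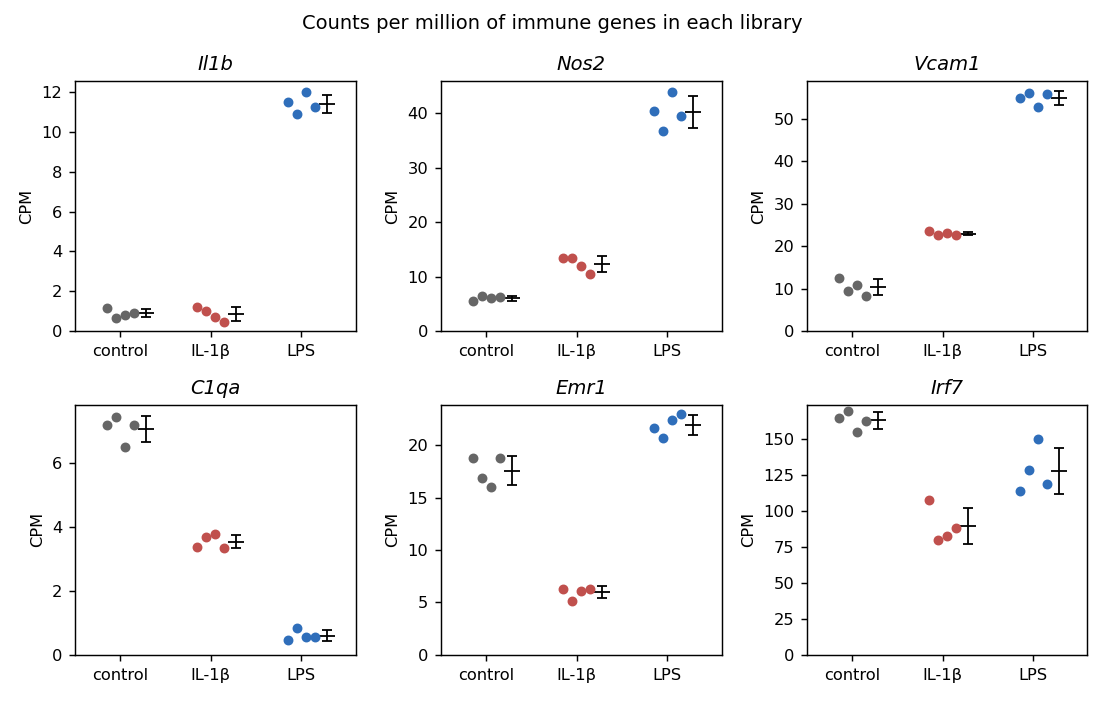
CPM of 6 immune genes in each of the 12 libraries, with points for libraries, a horizontal tick for the group mean and bars for the SD (n = 4 per group). Each vertical axis starts at 0. Il1b averaged 0.889 in control, 0.861 with IL-1β and 11.4 with LPS, whereas Emr1 averaged 17.6, 5.95 and 21.9.

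Macrophage markers were lower with LPS than with IL-1β in 12 of 19 and higher in 1, or 13 and 1 adjusted over the list alone (median -0.58, adjusted p = 8.63e-08, and 0.0167 as the adjusted p with an estimated correlation). Laptm5 was lower (-1.34 ± 0.11) and Emr1, the gene of the F4/80 antigen, was higher (1.88 ± 0.07). MHC class II genes were lower in 2 of 8, RT1-DMb (-1.99 ± 0.21) and RT1-DMa (-0.62 ± 0.16), and Cd74 was not past the threshold (-0.12 ± 0.13). That list's median of -0.47 had an adjusted p of 0.0434, lost at adjusted p = 0.136 with an estimated correlation, at 0.0638 with upper-quartile factors and at 0.0597 with library size alone, and lost without Control replicate 4 (-0.47), IL-1β replicate 2 (-0.32) or LPS replicate 1 (-0.41); without IL-1β replicate 1 the median was -0.30. Endothelial markers were lower in 15 of 16 with 0 higher (median -0.41, adjusted p = 4.98e-08, lost at adjusted p = 0.219 with an estimated correlation), among them Vwf (-0.91 ± 0.08), Flt1 (-0.60 ± 0.11), Mmrn2 (-0.50 ± 0.09) and Sox18 (-0.47 ± 0.09). Smooth muscle markers did not pass as a list, with 4 of 14 higher and 4 lower, or 5 and 7 adjusted over the list alone (median -0.00, adjusted p = 0.816); Tagln was higher (0.36 ± 0.04) and Des lower (-0.43 ± 0.05). The number higher was 2 without IL-1β replicates 1 or 3 or LPS replicate 2.

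Complement and acute phase genes were lower with LPS than IL-1β in 9 of 21 and higher in 2, or 11 and 2 adjusted over the list alone (median -0.18, adjusted p = 0.00794, lost at adjusted p = 0.284 with an estimated correlation). Serpina3n (-1.33 ± 0.16), A2m (-1.18 ± 0.10), whose row was nearly identical to that of an unnamed locus, and Lcn2 (-0.65 ± 0.03) were lower and C3 higher (0.42 ± 0.05). Proteases and inhibitors were lower in 12 of 27 and higher in 3, or 13 and 3 adjusted over the list alone (median -0.15, adjusted p = 0.00866, lost at adjusted p = 0.178 with an estimated correlation), with Mmp12 (-1.36 ± 0.11) and Timp1 (-0.38 ± 0.03) lower and Mmp9 (0.58 ± 0.09) higher. Neither Mmp3 (-0.40 ± 0.15) nor Mmp13 (-0.62 ± 0.36) was past the threshold, though Mmp3 was called without IL-1β replicate 2 (-0.51) or LPS replicate 1 (-0.53) and in 3 other settings. Collagen genes were lower in 10 of 30 and higher in 4, or 12 and 7 adjusted over the list alone (median -0.06, adjusted p = 0.146). The list passed without IL-1β replicate 1 or LPS replicate 4 (-0.08 for both), and 7 were higher without IL-1β replicate 4. Cell cycle lists did not pass, with 2 of 33 mitosis genes higher, or 1 adjusted over the list alone (median 0.03, adjusted p = 0.206), 3 of 32 DNA replication genes higher and 1 lower (0.04, adjusted p = 0.218), and 5 of 20 G1 genes higher and 2 lower, or 7 and 4 adjusted over the list alone (0.08, adjusted p = 0.146). The mitosis list passed without LPS replicate 1 (0.06). Its number higher was then 6, 5 without IL-1β replicate 3, 4 without LPS replicate 2, and 1 without Control replicates 2, 3 or 4, IL-1β replicates 1, 2 or 4 or LPS replicate 3. Mki67 (0.02 ± 0.04), Ccnb1 (0.07 ± 0.05), Ccnd1 (-0.19 ± 0.07) and Pcna (0.11 ± 0.05) were not past the threshold, though Ccnd1 was called without IL-1β replicate 2 (-0.24) and Pcna without IL-1β replicate 1 (0.16) or with no low-count filter (0.11).

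In all 1960 genes were higher and 1831 lower with LPS than IL-1β, 21.9% of those tested, with a median size of 0.22 on the log2 scale, and 45 and 94 of them differed at least 2-fold. Libraries of these groups did not overlap in 21.6% of genes, against 2.86% by chance. The number of calls was 2899 without LPS replicate 3 and 4069 without LPS replicate 1.

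Both stimuli were last compared in the genes they called against control. Called in both and higher in both were 2902 genes, where independent lists would share 961.1, and lower in both were 2768, where they would share 796.2. Opposite calls numbered 66, against 1750.1 for independent lists, and each of the 66 also differed between the treatments. They included Emr1 (-1.57 with IL-1β and 0.31 with LPS), Irg1 (-1.62 and 2.92), Clec10a (2.91 and -1.14), Csf1 (-0.37 and 0.40), Gbp2 (-0.20 and 0.28) and Psmb9 (-0.17 and 0.24). Of 2525 genes called with IL-1β alone 1072 differed between the treatments, and of 1622 called with LPS alone 672 did. Fold changes correlated across genes at 0.864, against 0.495 in simulated unchanged groups that share the controls, and genes are not independent replicates. With the controls divided between the treatments, 4040 to 4183 genes were shared in direction and 37 to 86 opposite. The correlation across genes was then 0.777 to 0.805.

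**Figure D4:**
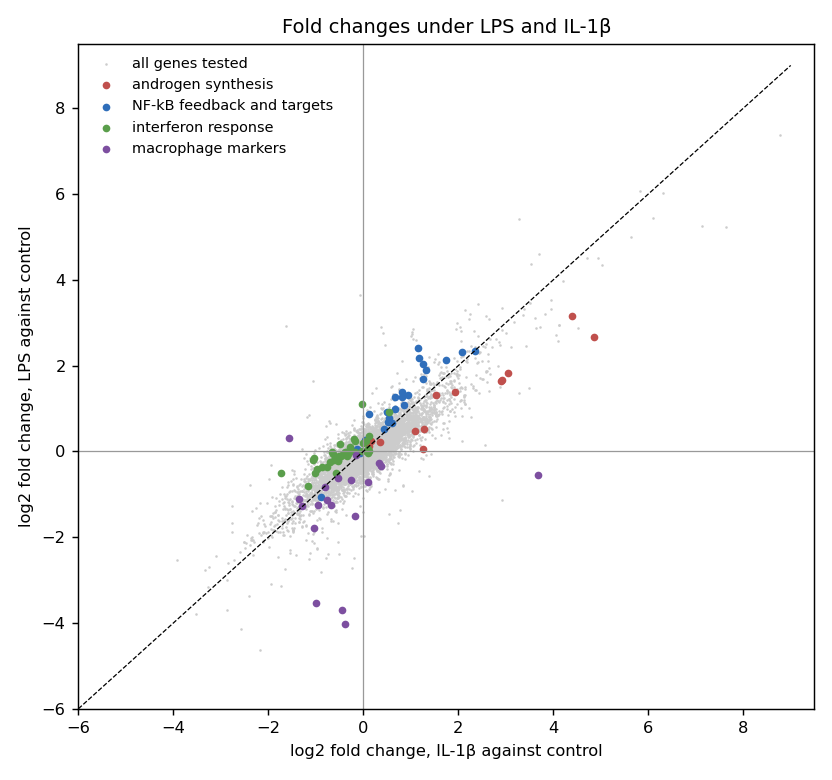
Log2 fold change with LPS (vertical axis) against log2 fold change with IL-1β (horizontal axis), both against control, for 17330 genes (grey) with 4 lists in colour. The dashed line marks equal values. NF-kB genes lie mostly above the line, with 18 of 24 higher under LPS, and androgen synthesis genes below it, with 9 of 13 lower.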

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

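The tests of the macrophage, endothelial and androgen synthesis patterns, and the genes C1qb, Cd163, Msr1, Cdh5 and Pecam1, were chosen only after the results were seen.

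Macrophage markers were lower in both treatments (median log2 fold change -1.11 with LPS and -0.54 with IL-1β, the second lost at adjusted p = 0.0806 with an estimated correlation), and no sort against leukocytes is named in the labels. Of their abundant members, Lyz2 and Cd68 averaged 27.4 and 17.8 CPM in control cultures and 7.97 and 7.49 CPM with LPS. Others did not share that fall: Emr1 (15.15 CPM over all libraries) rose with LPS. Msr1 (21.6 CPM) changed by -0.27 with LPS and by 0.33 with IL-1β. No member stands on another list, though bulk cultures do not show which of them theca cells also express. A loss of macrophages alone would lower the members by one factor, but 11 of 19 lay over 3 SE from the median with LPS, from -4.02 (C1qb) to 0.31 (Emr1). With IL-1β 12 of 19 did so, from -1.57 (Emr1) to 3.68 (Cd163), so neither fall had one common factor as its whole cause. A smaller number of macrophages may still account for part of it, and changed expression within macrophages under each stimulus stays open as an untested alternative.

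Endothelial markers were higher with IL-1β (median 1.07, lost at adjusted p = 0.237 with an estimated correlation), and abundant Cdh5 and Pecam1 went from 64.6 and 22.4 to 134.5 and 55.4 CPM. A smaller share of theca-interstitial cells would raise the mean log2 CPM of 6 other marker lists alike, as in granulosa cells (0.46 ± 0.11, SE, n = 4) and surface epithelium (0.32 ± 0.06). In the other 4 it was lower in every IL-1β library than in every control library, as in macrophages (-0.41 ± 0.04) and smooth muscle (-0.97 ± 0.03). Each had an exact permutation p of 0.0286 (adjusted p = 0.0286), the smallest the test can give. With an estimated correlation none of those 4 lists passed against other genes (0.0806 to 0.571 as adjusted p). The lymphocyte list, 1 of the 4, had a median of 0.02 and did not pass with the preset correlation either (adjusted p = 0.501). A list can fall with the theca share where theca cells express its members, which bulk cultures do not show. Tagln of the smooth muscle list had 48579 to 74073 counts per control library, so that list does not decide. Nor does the macrophage fall decide, since fewer macrophages or changed expression within them could lower those markers at any theca share. A smaller theca share as the whole cause of the endothelial rise therefore stays open. For a larger endothelial share, 5 of 16 members lay over 3 SE from the median, too many for one factor and too few to exclude it, so this and changed expression cannot be told apart. Within groups the members varied together (mean correlation 0.617, against 0.0651 at the 95th percentile of 1000 random lists), which is consistent with an endothelial share that differs between cultures, but the interferon list, which marks no cell type, reached 0.667.

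Between the treatments, androgen synthesis genes were lower and NF-kB genes higher with LPS than IL-1β. Of 925 genes outside both lists that both treatments raised and that differed between them, 711 were lower with LPS. A weaker form of one response would give that. The other 214 were higher, 10 of them at least 2-fold. The adjusted p limits false calls over all genes tested, not within this set, so the number of false calls among the 214 is not known. They argue against a weaker form as the whole cause only so far as they are not false calls. Other scalings moved all genes by at most -0.0117 on the log2 scale, and without the Hsd3b copies the androgen list kept a median of -0.57 with 6 of 10 lower, so neither scaling nor reads shared between those copies accounts for it. As a hypothesis found and tested on the same data, the stimuli may differ in the balance of these gene groups. The dose of IL-1β is not clearly stated, so a difference in dose stays open.

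In 39 of 705 groups of 4 values, 1 library lay apart from the other 3, by a gap whose share of the group's range passed Dixon's 95% critical value, where chance gives about 1 in 20, or 35.2. In the control group, replicate 1 lay apart for Ccnb1 (gap ratio 0.885), Ctgf (0.859), Irak2 (0.851), Ccl12 (0.842) and Bcl3 (0.833). Control replicate 2 did for Il10 (0.964), Tlr2 (0.928) and RT1-Db1 (0.882), and Control replicate 3 for Mmp13 (0.903), Abcg1 (0.878), Psmb8 (0.874), Pfkp (0.872) and Plin4 (0.843). Control replicate 4 stood apart in Des (0.935), Nr4a1 (0.876) and Laptm5 (0.841). Among IL-1β libraries, replicate 1 lay apart for Fam180a (0.963), Lcn2 (0.926), Ifi44l (0.857), Irf1 (0.835) and Loxl2 (0.833), replicate 2 for Krt8 (0.955) and Cdk1 (0.859), and replicate 3 for Insl3 (0.875) and Mmrn2 (0.865). IL-1β replicate 4 did for Sox18 (0.952), Myh11 (0.928), Fabp4 (0.907), Lmod1 (0.861) and Ddx4 (0.841). With LPS, replicate 1 lay apart for Mmp9 (0.967) and Gpi (0.897), replicate 2 for Cxcl12 (0.895), and replicate 3 for Idi1 (0.953), Mmp12 (0.904), Loxl2 (0.876), Mki67 (0.86), Plin4 (0.85) and Ccl12 (0.848).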

How the results depend on the processing

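The tests of the comparisons, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined. Lists with upper-quartile factors or library size alone, which ended 3 list calls and added 1, numbers of list members with 1 library left out, and the tests of the macrophage, endothelial and androgen synthesis patterns were added after seeing the data. The counts of genes higher and lower in each comparison stayed within 1.5 times under the other scalings, filters and tools, the fits on 8 libraries and each library left out. The exceptions were stricter thresholds: at least 2-fold left 666 and 409 genes with IL-1β, 398 and 387 with LPS, and 45 and 94 between treatments, where an adjusted p under 0.01 left 1137 and 1065. With an estimated correlation 2 of 16 lists stayed past the threshold with IL-1β, 7 of 14 with LPS and 3 of 15 between treatments. With 1 library left out, 7633 to 8459 genes were called with IL-1β, 6628 to 7350 with LPS and 2899 to 4069 between treatments. With a replicate block the counts were 4392 and 4152, 4076 and 3654, and 2176 and 2080, but the numbers were not taken to pair the libraries, since 4 of 12 same-numbered pairs correlated above 0.1 (0.008 to 0.199, other numbers -0.163 to 0.085). In 8 of 12 a library correlated best with its own number, a hint from the data, not the design. Of the 35 splits of 8 libraries, 1, the real one, gave as many calls in each comparison. It gave 8534 with IL-1β against 0 in the highest other, 7109 with LPS against 0 and 3361 between treatments against 1. A share of 1 in 35 is the smallest this test can give, so it argues against a chance division of these libraries without excluding it. It does not cover chance between cell preparations. Of named gene results, 7 of 142 calls with IL-1β, 8 of 138 with LPS and 5 of 114 between treatments were lost in some setting, 3, 1 and 11 were gained, and no called gene reversed. With 1 library left out, values without a call crossed 0 for Il1b with IL-1β (-0.29 to 0.12), Il1rn with LPS (-0.067 to 0.15), and Insl3 (-0.34 to 0.085) and Mki67 (-0.038 to 0.041) between treatments; the cause was not tested. Where fry passed the threshold, the lists for nitric oxide (median -0.11), surface epithelium (0.58), TLR and IL-1 signalling (0.02) and lymphocytes (0.02) with IL-1β, and surface epithelium with LPS (0.17), leaned the other way from their medians; the cause was not tested. Of numbers of list members past the threshold, 14 that were 0 to 2 moved by 1 with some library left out. Small changes can be missed: in the smallest simulated class, 48% were called with IL-1β and 56% with LPS. With 25 of 17330 genes changed per class, that simulation held far fewer changed genes than were called in the data. These shares may therefore be lower than for the data, and depth and replicate number were not varied.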

Other observations

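The lists with library size alone, and numbers of members with 1 library left out, were tested only after the results were seen. Glycolysis and glucose uptake genes rose with IL-1β in 16 of 25 and fell in 5 (median 0.26, adjusted p = 0.0153, lost at adjusted p = 0.5 with an estimated correlation). Slc2a3, a glucose transporter gene whose row was nearly identical to that of an unnamed locus, rose by 1.27 ± 0.05 on the log2 scale (SE, 4 libraries per group), Pfkm by 0.44 ± 0.04 and Pkm by 0.44 ± 0.04, and Pfkp fell (-0.54 ± 0.03). With LPS 9 rose and 6 fell, or 10 and 6 adjusted over the list alone (median 0.11, adjusted p = 0.493), and 15 were lower and 1 higher than with IL-1β, or 16 and 1 adjusted over the list alone (-0.15, adjusted p = 1.32e-04, lost at adjusted p = 0.284 with an estimated correlation). Prostaglandin genes rose in 9 of 20 and fell in 5 with IL-1β (0.24, adjusted p = 0.14), and rose in 8 and fell in 4 with LPS, or 10 and 4 adjusted over the list alone (0.28, adjusted p = 0.112). The prostaglandin carrier gene Slco2a1 rose by 2.88 ± 0.11 and 2.49 ± 0.11, and Pla2g5 by 2.05 ± 0.17 and 2.58 ± 0.16. Between treatments 6 were higher and 6 lower (median 0.03 and mean -0.15, adjusted p = 0.891), with Ptgds lower under LPS (-2.00 ± 0.37). Among nitric oxide and oxidant defence genes 10 of 28 rose and 12 fell with IL-1β, or 10 and 13 adjusted over the list alone (median -0.11 and mean 0.17, adjusted p = 0.801), and 9 rose and 9 fell with LPS (0.01, adjusted p = 0.701). Arg1, which degrades arginine, rose by 3.39 ± 0.15 and 3.32 ± 0.15, Gpx3, a secreted peroxidase, by 0.88 ± 0.06 with IL-1β, and Ncf1 was lower (-1.55 ± 0.07 and -1.10 ± 0.07). Between treatments 4 were higher and 3 lower (0.06, adjusted p = 0.16).

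TLR and IL-1 signalling genes went both ways, 8 of 30 higher and 13 lower with IL-1β, or 9 and 13 adjusted over the list alone (median 0.02 while camera leaned downward, adjusted p = 0.526), and 9 and 9 with LPS, or 10 and 9 adjusted over the list alone (0.02, adjusted p = 0.844). Tlr2, a receptor for bacterial lipoproteins, rose with LPS (1.49 ± 0.07), and the brake Irak3 rose by 0.99 ± 0.07 with IL-1β and 1.10 ± 0.07 with LPS. Between treatments 10 were higher and 2 lower under LPS, or 10 and 3 adjusted over the list alone (0.06, adjusted p = 0.0171, lost at adjusted p = 0.136 with an estimated correlation); without LPS replicate 2 that median was 0.09. Cholesterol storage genes rose in 6 of 17 and fell in 4 with IL-1β, or 7 and 5 adjusted over the list alone (0.09, adjusted p = 0.56), and rose in 4 and fell in 5 with LPS, or 5 and 6 adjusted over the list alone (0.04, adjusted p = 0.962). The number lower with LPS was 3 without Control replicate 2. Vldlr fell in both (-1.34 ± 0.03 and -1.33 ± 0.03) and the cholesterol exporter Abcg1 rose (1.31 ± 0.08 and 1.07 ± 0.08). Between treatments 3 were higher and 3 lower, or 4 and 4 adjusted over the list alone (-0.07, adjusted p = 0.279), with 1 higher without IL-1β replicate 3 or LPS replicates 3 or 4. Immediate early and heat shock genes rose in 10 of 25 and fell in 8 with IL-1β (0.05, adjusted p = 0.647), rose in 9 and fell in 8 with LPS, or 11 and 8 adjusted over the list alone (0.05, adjusted p = 0.844), and between treatments 3 were higher and 6 lower, or 6 and 6 adjusted over the list alone (-0.04, adjusted p = 0.283), with 7 higher without LPS replicate 4. Junb rose by 0.89 ± 0.04 and 0.84 ± 0.04, and Hspb1 fell (-0.78 ± 0.04 and -0.79 ± 0.04).

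Markers of further cell types were also measured. Granulosa cell markers, of which Cyp19a1, Hsd17b1 and Inha also stand on other lists, rose in 9 of 14 and fell in 2 with IL-1β (0.52, adjusted p = 0.0325, lost at adjusted p = 0.433 with an estimated correlation, at 0.073 with library size alone, and without Control replicate 1 (0.50) or IL-1β replicate 2 (0.48)), with Inha at 0.94 ± 0.12, Fshr at 0.81 ± 0.15 and Gja1 at 0.58 ± 0.03. Amh, another member, went the other way, with 30 to 56 counts per control library and 10 to 27 per IL-1β library. With LPS 5 of the 14 rose, or 3 without LPS replicate 1, and 2 fell (0.08, adjusted p = 0.553), and 6 were lower than with IL-1β with 0 higher, or 7 and 1 adjusted over the list alone (-0.27, adjusted p = 0.00794, lost at adjusted p = 0.284 with an estimated correlation). Oocyte markers fell in 3 of 13 with IL-1β, or 0 adjusted over the list alone (-0.52, adjusted p = 0.0293, lost at adjusted p = 0.571 with an estimated correlation and without IL-1β replicate 4 (-0.42)), among them the egg coat gene Zp2 (-0.56 ± 0.15). The number lower was 1 without Control replicates 2 or 4 or IL-1β replicates 3 or 4, 6 without LPS replicate 2 and 7 without LPS replicate 4. They fell in 4 with LPS (-0.57, adjusted p = 0.00621, lost at adjusted p = 0.57 with an estimated correlation), or in 1 without Control replicate 1 or LPS replicate 3, 2 without Control replicate 2 or LPS replicate 4, and 11 without LPS replicate 2. Between treatments 0 passed (-0.03, adjusted p = 0.541). Surface epithelium markers rose in 4 of 11 and fell in 3 in either treatment (0.58, adjusted p = 0.576 with IL-1β, and 0.17, adjusted p = 0.975 with LPS, where camera leaned downward), with Msln, a mesothelial antigen, at 3.17 ± 0.25 and 3.02 ± 0.25, and the keratins Krt18 (-2.01 ± 0.09 and -2.02 ± 0.09) and Krt8 (-1.21 ± 0.07 and -1.26 ± 0.07) lower. Between treatments 0 passed (-0.14, adjusted p = 0.218). Lymphocyte markers rose in 1 of 7 and fell in 2 with IL-1β (median 0.02 and mean -0.20, adjusted p = 0.501), fell in 2 with LPS (-0.46, adjusted p = 0.0797, past the threshold without LPS replicate 2 (-0.70) or with library size alone (-0.42)), and differed in 1 between treatments (-0.19, adjusted p = 0.289). Cd4, which rat macrophages also carry, fell in both (-1.47 ± 0.08 and -1.27 ± 0.08).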
